A study of Mus musculus with 18 samples.

How the data were processed

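RNA from mouse kidney was sequenced in 18 libraries, 3 for each of 6 groups: sham surgery and cold-storage-associated kidney transplantation at day 1, day 7 and day 14. Group, day and replicate number were taken from the sample titles. Per the labels, total RNA was extracted from renal cortex with Trizol. The labels also name a rat proximal tubule cell line and a protocol of diabetes with ischemia and reperfusion, which do not match the titles, so the groups follow the titles and nothing else in those fields was used. The organism and tissue fields name mouse and kidney, and mouse gene identifiers fill the table. The labels used here do not state strain, sex, donor and recipient, or the time in the cold.

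The deposited table holds FPKM (fragments scaled to gene length and to the library total) per gene and library, as made by the authors. The submitters' processing notes name DESeq2, with no role, and the genome build mm10, and the aligner, the quantifier and the annotation are not given in the sources used here. Low values were not whole multiples of the value of 1 fragment (7.79% to 9.86% whole within a tolerance of 0.05), so no reads were recovered, and depth and the precision it gives are unknown.

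Capital N and A were missing from the identifiers and symbols of the table. Identifiers were repaired by restoring the fixed start of mouse gene identifiers, and 54819 of 54848 matched the GENCODE M21 annotation of GRCm38, the same assembly as mm10, which gave symbols, coordinates, exon length and GC content. Of the deposited symbols, 54239 equalled the annotation's symbol once N and A were removed from it, and 27 had become spreadsheet dates. The 7 identifiers on more than 1 row (17 rows) were left out, and where several identifiers shared a symbol the most abundant kept it. No 2 libraries held the same values, and all value columns were mapped to a library.

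Genes with FPKM of at least 1 in at least 3 libraries were kept (15278), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 as 6 group means over all 18 libraries, with empirical Bayes moderation that was robust and followed the mean. Contrasts were transplant against sham at each day, the differences of these effects between days, and sham between days. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. The 46 gene lists, with 1008 entries, were written before the data were examined, from general knowledge of kidney cell types and pathways, and lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and at an estimated one. A p beside a list is adjusted over lists within a day.

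Genes were named by a rule fixed before the data were examined: per day and direction, the 8 largest changes among called genes with a mean FPKM of at least 5 whose 3 transplant libraries all lay above or all below the 3 sham libraries; per list and day, up to 3 called genes with the smallest adjusted p; a fixed panel of genes; and per difference and sham contrast, the 5 largest called changes in each direction. Predicted genes and clone names were left out. Genes of lists given as counts only are in part not named, and some genes picked by the rule are not reported here.

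The scaling of FPKM differs from one that balances all genes, and the report gives counts under both. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, moderation that was not robust, only the groups compared, array weights, the replicate number as a block, a log2 fold change of at least 1, and each library left out in turn. Chosen after seeing the data were FPKM rescaled without genes of the mitochondrial chromosome, without the 100 genes most abundant in sham, and to the same sum in every library (TPM scale). The limma step was tested on simulated data for the day 1 comparison over 15278 genes, with 50 genes changed per size. It recovered 4% of changes of 0.5 on the log2 scale, 62% of changes of 1, 96% of changes of 2 and 90% of changes of 4, with 5 unchanged genes called. Simulated values below 0 were set to 0, which shortened large falls. Far fewer genes changed there than were called at day 1 (5977), which makes the adjusted p stricter. These shares therefore do not give the power of the real comparison. Tables were handled with Python 3.11.15 and figures drawn with matplotlib 3.10.9.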

Results

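Kidney RNA from mice was sequenced after kidney transplantation associated with cold storage, in which the donor organ is kept cold before it is implanted, and after sham surgery. The 18 libraries formed 6 groups of 3: sham and transplant at day 1, day 7 and day 14. Each day had its own sham group, and n = 3 libraries per group holds for every mean, SD and test here. The labels number the libraries but do not say that they came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The deposited values are FPKM, and the sums per library ran from 386876 to 524362. Sequencing depth is unknown, and no interval that needs it is given. Genes above 0 numbered 18666 to 23088 per library. After a filter on low values, 15278 genes were tested, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene low in sham can pass the filter through transplant libraries alone. Shares of a gene list are shares of its tested genes and can therefore overstate how much of the list rose.

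Transplant libraries stood apart from sham libraries along the first principal component, which held 47.2% of the variance, and transplant libraries of day 1 stood apart from those of day 7 and day 14 along the second, which held 14.5%. Transcripts of the mitochondrial chromosome took 29.3% ± 0.837, 30.3% ± 0.627 and 30.7% ± 0.730 (SD) of the FPKM sum in sham at day 1, day 7 and day 14, and 22.0% ± 4.39, 16.5% ± 1.85 and 25.7% ± 2.42 in transplant. The median log2 fold change of all tested genes, transplant over sham, was 0.31 at day 1, 0.41 at day 7 and 0.27 at day 14. A gene at these values therefore held its place among all genes, and counts of genes higher and lower after transplantation are given beside those under median-of-ratios scaling, where the medians were 0.05, 0.07 and 0.07.

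**Figure D1:**
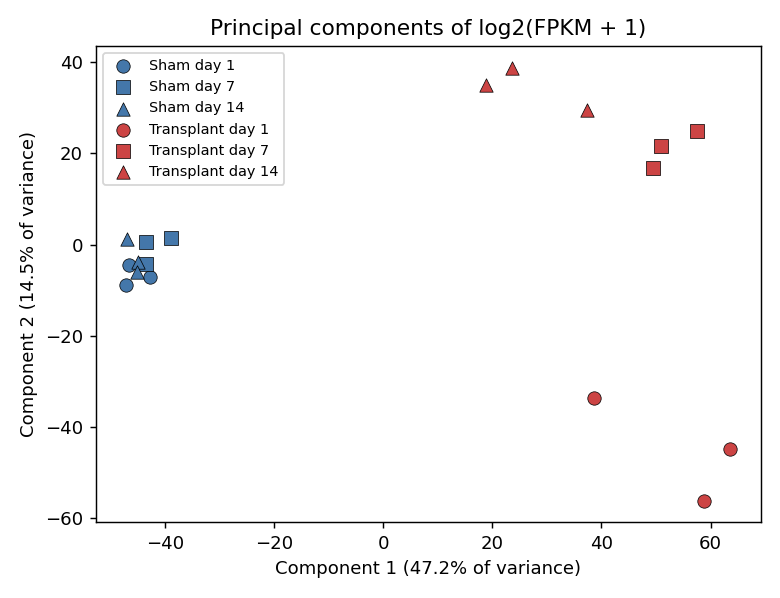
Each point is 1 of the 18 libraries, placed by its score on the first component (horizontal, 47.2% of the variance) and the second component (vertical, 14.5%) of log2(FPKM + 1), with colour for surgery and shape for day. The 9 sham libraries lie together and the transplant libraries lie apart from them.

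At day 1, the comparison of transplant with sham asks what the kidney expresses soon after implantation. Of the genes picked by the naming rule, Havcr1, Krt20 and Lcn2 rose most. Havcr1, a marker of tubular injury, which encodes kidney injury molecule 1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578 in GRCm38), measured 1057 ± 219 FPKM in transplant against 0.663 ± 0.0981 FPKM in sham, a log2 fold change of 9.29 ± 0.20 (SE, limma adjusted p = 9.00e-16). Lcn2, which encodes the iron-carrier-binding protein NGAL, measured 278 ± 76.4 FPKM in transplant against 0.159 ± 0.0718 FPKM in sham, and Spp1, which encodes osteopontin, measured 9331 ± 1148 FPKM in transplant against 325 ± 15 FPKM in sham. Genes of transport, solute handling and glucose synthesis in the tubule fell. Egf, made by the distal nephron (ENSMUSG00000028017, chromosome 3, 129677565 to 129755316), measured 5.59 ± 0.345 FPKM in transplant against 302 ± 51.8 FPKM in sham. In total 4517 genes were higher and 1460 lower (75.6% of calls higher), against 2365 higher and 2285 lower (50.9%) under median-of-ratios scaling.

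Of the 30 tested tubular injury genes, 30 rose and 0 fell (30 and 0 adjusted over the list alone, 29 and 0 under median-of-ratios scaling), with a camera adjusted p = 8.69e-25 and an adjusted p = 0.0268 with an estimated correlation. Log2 fold changes (± SE) of other large rises were Krt20 8.5 ± 0.36, Sprr1a 6.19 ± 0.46, Akr1b8 5.47 ± 0.28 and S100a6 5.38 ± 0.28, and those of Hmga1 and Flnc were 5.19 ± 0.32 and 5.07 ± 0.27 (limma adjusted p at most 9.54e-09). Sham libraries held Krt20, Lcn2 and Flnc near 0, so these fold changes depend on the pseudocount. Of the 40 tested proximal tubule transporter genes, 1 rose and 35 fell (1 and 35 adjusted over the list alone, 1 and 36 under median-of-ratios scaling), with a camera adjusted p = 1.84e-31 and an adjusted p = 0.0268 with an estimated correlation. Examples were Slc7a13 -4.42 ± 0.16 and Slc5a8 -3.14 ± 0.15, and Slc34a1, the sodium-phosphate cotransporter, at -2.70 ± 0.18. Of the 35 tested genes of solute and drug metabolism, 0 rose and 33 fell (0 and 33 adjusted over the list alone, 0 and 33 under median-of-ratios scaling), with a camera adjusted p = 3.07e-37 and an adjusted p = 0.0167 with an estimated correlation. Among them were Acy3 -3.09 ± 0.19 and Mep1a -2.44 ± 0.15. Other named genes, in these lists or outside them, were Mep1b, Cyp7b1, Slc22a22, Slc22a19 and Akr1c14 at -5.16 ± 0.39, -4.39 ± 0.41, -4.32 ± 0.30, -4.19 ± 0.38 and -4.18 ± 0.32 (limma adjusted p at most 1.51e-07).

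Of the 8 tested gluconeogenesis genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone, 1 and 7 under median-of-ratios scaling), with a camera adjusted p = 1.39e-07 and an adjusted p = 0.0455 with an estimated correlation. G6pc, the last enzyme of glucose release, was at -4.26 ± 0.41 and Fbp1 at -2.64 ± 0.23. Of the 62 tested nuclear genes of oxidative phosphorylation, 0 rose and 44 fell (0 and 50 adjusted over the list alone, 0 and 57 under median-of-ratios scaling), with a camera adjusted p = 1.24e-22 and an adjusted p = 0.133 with an estimated correlation. Ndufs1, of complex I, was at -1.01 ± 0.11 and Sdha, of complex II, at -0.98 ± 0.12. Of the 13 tested genes of the mitochondrial chromosome, 0 rose and 12 fell (0 and 13 adjusted over the list alone, 0 and 13 under median-of-ratios scaling), with a camera adjusted p = 4.93e-07 and an adjusted p = 0.252 with an estimated correlation. Under quantile normalization the list did not pass camera (adjusted p = 0.392). That normalization gives each rank the same value in every library, so it can hide a fall of genes that stay among the most abundant. Nuclear copies of mitochondrial sequence can share reads with these genes. Of the 38 tested fatty acid oxidation genes, 9 rose and 15 fell (9 and 15 adjusted over the list alone, 2 and 21 under median-of-ratios scaling), with a camera adjusted p = 2.77e-05 and an adjusted p = 0.19 with an estimated correlation. Acsm3 was at -3.41 ± 0.22. Cpt1a, the carnitine shuttle enzyme, was at -0.21 ± 0.16 and did not pass the test, though it did under median-of-ratios scaling (-0.56, limma adjusted p = 0.00867). Ppargc1a, a coactivator of mitochondrial biogenesis, was lower, at -1.08 ± 0.17.

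Genes of the distal segments that passed the test at day 1 were mostly lower. Of the 16 tested thick ascending limb genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone, 0 and 12 under median-of-ratios scaling), with a camera adjusted p = 6.32e-10 and an adjusted p = 0.0438 with an estimated correlation. Slc12a1, the loop diuretic target, was at -2.72 ± 0.20, while Umod, the urinary glycoprotein of the same segment, was at 0.25 ± 0.17 and did not pass the test. Of the 13 tested distal convoluted and connecting tubule genes, 0 rose and 10 fell (0 and 12 adjusted over the list alone, 0 and 12 under median-of-ratios scaling), with a camera adjusted p = 1.30e-11 and an adjusted p = 0.0268 with an estimated correlation. Pvalb and Calb1, both calcium-binding proteins, were at -3.77 ± 0.22 and -3.53 ± 0.20. Of the 16 tested intercalated cell genes, 0 rose and 10 fell (0 and 11 adjusted over the list alone, 0 and 11 under median-of-ratios scaling), with a camera adjusted p = 4.93e-07 and an adjusted p = 0.0379 with an estimated correlation. Of the 13 tested principal cell genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone, 0 and 4 under median-of-ratios scaling), with a camera adjusted p = 0.0312 and an adjusted p = 0.365 with an estimated correlation.

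Of the 19 tested NRF2 target genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, 10 and 3 under median-of-ratios scaling), with a camera adjusted p = 0.00573 and an adjusted p = 0.118 with an estimated correlation. Srxn1 and Gsta1 were at 3.43 ± 0.15 and 3.61 ± 0.20. Of the 18 tested p53 target genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, 9 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.00325 and an adjusted p = 0.175 with an estimated correlation. Cdkn1a, a cell cycle inhibitor, was at 3.65 ± 0.35. Of the 22 tested cell death genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone, 8 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.0129 and an adjusted p = 0.205 with an estimated correlation. Mlkl, the effector of necroptosis, was at 3.02 ± 0.33. Of the 16 tested immediate early genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone, 10 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.00843 and an adjusted p = 0.389 with an estimated correlation. With a mean FPKM of at least 5, the p53 and immediate early lists did not pass camera (adjusted p = 0.138 and 0.0568). Of the 14 tested heat shock genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, 3 and 2 under median-of-ratios scaling), with a camera adjusted p = 0.272 and an adjusted p = 0.586 with an estimated correlation. Hspb1 was at 4.48 ± 0.33. Of the 26 tested genes of the unfolded protein and integrated stress responses, 10 rose and 3 fell (10 and 3 adjusted over the list alone, 6 and 6 under median-of-ratios scaling), with a camera adjusted p = 0.809 and an adjusted p = 0.902 with an estimated correlation. Of the 20 tested hypoxia response genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone, 4 and 8 under median-of-ratios scaling), with a camera adjusted p = 0.22 and an adjusted p = 0.461 with an estimated correlation. Of the 50 tested ribosomal protein genes, 49 rose and 0 fell (49 and 0 adjusted over the list alone, 39 and 0 under median-of-ratios scaling), with a camera adjusted p = 3.75e-14 and an adjusted p = 0.205 with an estimated correlation. Rpl12 and Rps18 were at 1.99 ± 0.19 and 1.01 ± 0.11. Of the 38 tested extracellular matrix genes, 29 rose and 1 fell (29 and 1 adjusted over the list alone, 25 and 2 under median-of-ratios scaling), with a camera adjusted p = 2.50e-06 and an adjusted p = 0.365 with an estimated correlation. Col1a1 was at 2.75 ± 0.30.

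At day 1, no immune list passed camera with an estimated correlation. Of the 7 tested neutrophil genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 6 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.0124 and an adjusted p = 0.205 with an estimated correlation. S100a9 and S100a8 were at 4.79 ± 0.43 and 3.89 ± 0.63. Of the 24 tested cytokine and chemokine genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone, 12 and 3 under median-of-ratios scaling), with a camera adjusted p = 0.0381 and an adjusted p = 0.461 with an estimated correlation. Cxcl1, which attracts neutrophils, was at 5.04 ± 0.31, and Ccl2, which attracts monocytes and was listed at 0 in the 3 sham libraries, measured 2.82 ± 2.02 FPKM in transplant. Of the 26 tested monocyte and macrophage genes, 9 rose and 2 fell (11 and 2 adjusted over the list alone, 7 and 2 under median-of-ratios scaling), with a camera adjusted p = 0.134 and an adjusted p = 0.586 with an estimated correlation. Under median-of-ratios scaling this list passed camera (adjusted p = 0.0155). Cd14 was at 3.54 ± 0.26, and Adgre1, the macrophage marker F4/80, was at 0.37 ± 0.29 and did not pass the test. Of the 25 tested type I interferon response genes, 15 rose and 0 fell (17 and 1 adjusted over the list alone, 9 and 2 under median-of-ratios scaling), with a camera adjusted p = 0.0239 and an adjusted p = 0.365 with an estimated correlation. Of the 18 tested MHC class I presentation genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, 8 and 2 under median-of-ratios scaling), with a camera adjusted p = 0.0158 and an adjusted p = 0.42 with an estimated correlation. Of the 10 tested MHC class II presentation genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 4 under median-of-ratios scaling), with a camera adjusted p = 0.168 and an adjusted p = 0.586 with an estimated correlation. Of the 15 tested complement genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, 3 and 1 under median-of-ratios scaling), with a camera adjusted p = 0.809 and an adjusted p = 0.902 with an estimated correlation. C3, the central complement component, was at 3.50 ± 0.35. With a mean FPKM of at least 5, the cytokine, type I interferon and MHC class I lists did not pass camera (adjusted p = 0.0608, 0.179 and 0.0562), nor did the first 2 without transplant day 1 replicate 1 (adjusted p = 0.107 and 0.0863), nor type I interferon without sham day 1 replicate 2 (adjusted p = 0.0633). Members of the H2 family share sequence, so reads of single members are uncertain.

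**Figure D2:**
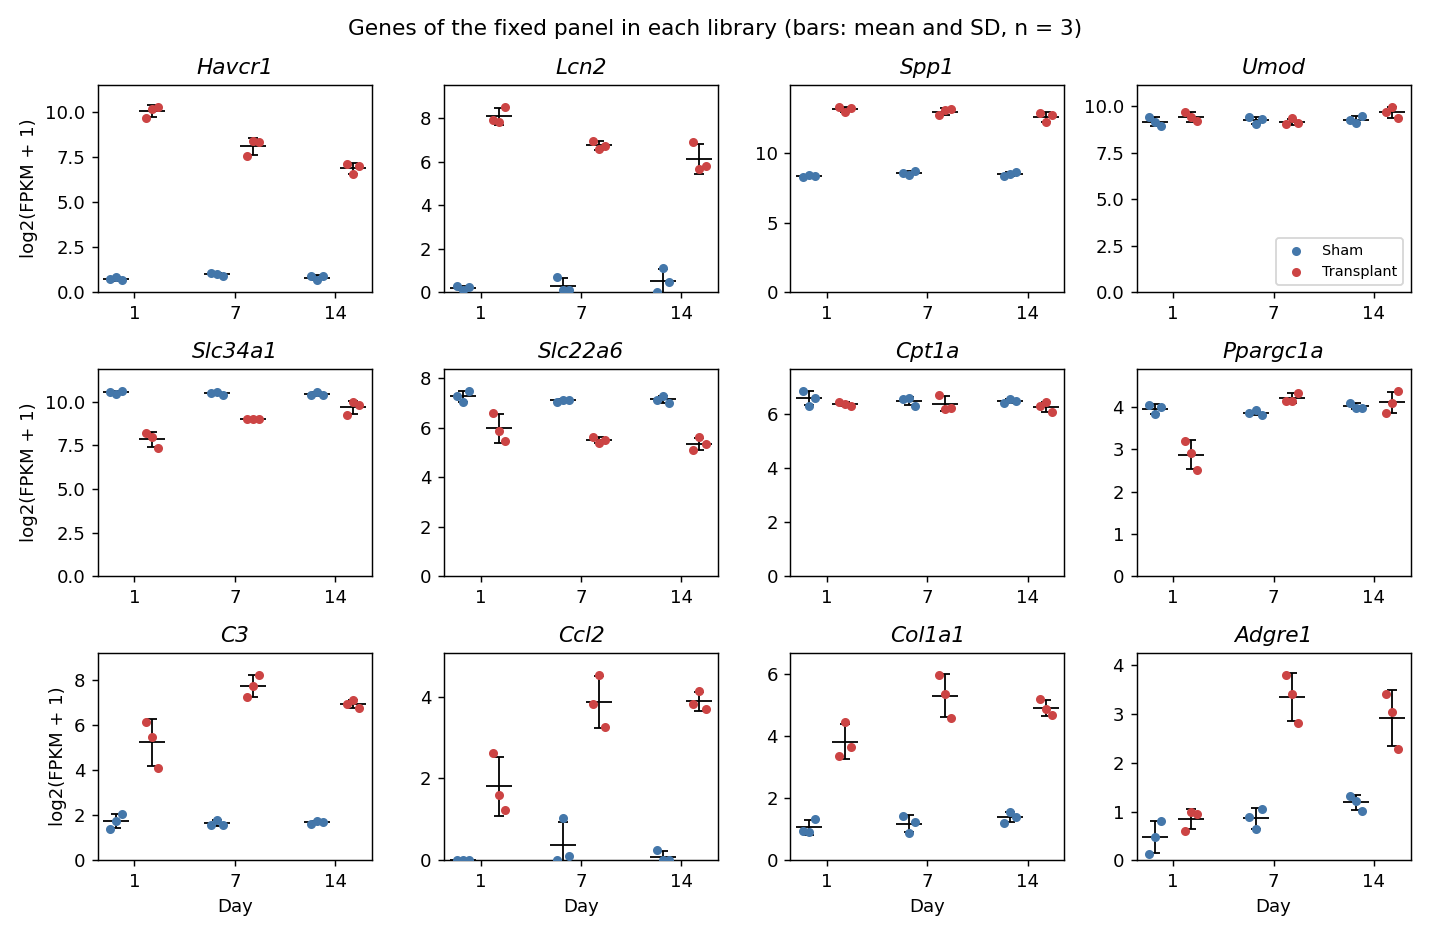
Each point is 1 library's log2(FPKM + 1) for 12 genes of the fixed panel, by day (horizontal) and surgery (colour), with bars for the mean and SD of 3 libraries. Havcr1, Lcn2 and Spp1 in transplant lie above sham at each of the 3 days, and Umod and Cpt1a overlap between surgeries.

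At day 7, 30 of 30 injury, 38 of 38 matrix, 35 of 35 cell cycle, 24 of 26 macrophage and 13 of 15 complement genes were higher than in sham. With an estimated correlation, camera kept the injury list but not matrix, cell cycle, macrophage or complement (adjusted p = 0.109, 0.201, 0.0565 and 0.0565). Of 40 transporter genes of the proximal tubule, 25 were lower. Havcr1 measured 281 ± 82.1 FPKM in transplant against 0.98 ± 0.0933 FPKM in sham (log2 fold change 7.11 ± 0.20, SE, limma adjusted p = 5.16e-14). C3 measured 220.0 ± 74.7 FPKM in transplant against 2.13 ± 0.277 FPKM in sham, and Vcam1, an adhesion molecule, measured 63.1 ± 1.20 FPKM in transplant against 1.53 ± 0.492 FPKM in sham. Slc7a13, an amino acid transporter of the proximal tubule, measured 3.24 ± 0.570 FPKM in transplant against 301 ± 10.3 FPKM in sham. In total 5418 genes were higher and 918 lower (85.5% of calls higher), against 1985 higher and 1790 lower (52.6%) under median-of-ratios scaling.

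Of the 38 tested extracellular matrix genes, 38 rose and 0 fell (38 and 0 adjusted over the list alone, 35 and 0 under median-of-ratios scaling), with a camera adjusted p = 6.00e-18 and an adjusted p = 0.109 with an estimated correlation. Col3a1, Col1a1 and Thbs1 were at 3.71 ± 0.27, 4.12 ± 0.30 and 2.64 ± 0.15. Of the 26 tested monocyte and macrophage genes, 24 rose and 0 fell (24 and 0 adjusted over the list alone, 23 and 0 under median-of-ratios scaling), with a camera adjusted p = 2.05e-11 and an adjusted p = 0.0565 with an estimated correlation. C1qc, Cx3cr1 and Adgre1 were at 3.03 ± 0.28, 2.23 ± 0.21 and 2.48 ± 0.29, and the lysozyme gene Lyz2 was at 4.56 ± 0.44. Of the 15 tested complement genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone, 10 and 2 under median-of-ratios scaling), with a camera adjusted p = 4.60e-05 and an adjusted p = 0.0565 with an estimated correlation. Of the 10 tested MHC class II presentation genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone, 8 and 0 under median-of-ratios scaling), with a camera adjusted p = 1.31e-04 and an adjusted p = 0.165 with an estimated correlation. Cd74 and H2-Aa were at 2.40 ± 0.20 and 2.17 ± 0.23, in the same libraries in which macrophage genes were higher. Of the 35 tested cell cycle genes, 35 rose and 0 fell (35 and 0 adjusted over the list alone, 27 and 0 under median-of-ratios scaling), with a camera adjusted p = 8.38e-07 and an adjusted p = 0.201 with an estimated correlation. Rrm2 and Mki67 were at 2.81 ± 0.31 and 1.78 ± 0.30. Genes low in sham, such as Mki67, can pass the filter through transplant libraries alone, so 35 of 35 is not a share of the whole list. Of the 24 tested cytokine and chemokine genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone, 16 and 1 under median-of-ratios scaling), with a camera adjusted p = 2.26e-04 and an adjusted p = 0.209 with an estimated correlation. Ccl2 was at 3.49 ± 0.35. Of the 7 tested neutrophil genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, 4 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.166 and an adjusted p = 0.423 with an estimated correlation. Under median-of-ratios scaling this list passed camera (adjusted p = 0.0156).

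Of the 30 tested tubular injury genes, 30 rose and 0 fell (30 and 0 adjusted over the list alone, 29 and 0 under median-of-ratios scaling), with a camera adjusted p = 8.23e-23 and an adjusted p = 0.0475 with an estimated correlation. Lcn2, S100a6, Spp1 and Cp, the copper-carrying ferroxidase, were at 6.47 ± 0.31, 5.01 ± 0.28, 4.41 ± 0.16 and 4.40 ± 0.21. Of the 40 tested proximal tubule transporter genes, 3 rose and 25 fell (4 and 26 adjusted over the list alone, 1 and 31 under median-of-ratios scaling), with a camera adjusted p = 7.63e-25 and an adjusted p = 0.0494 with an estimated correlation. Slco1a1 was at -4.87 ± 0.22, Slc34a1 at -1.48 ± 0.18 and Slc22a6, the organic anion transporter OAT1, at -1.59 ± 0.21. Of the 35 tested genes of solute and drug metabolism, 1 rose and 25 fell (2 and 26 adjusted over the list alone, 0 and 30 under median-of-ratios scaling), with a camera adjusted p = 1.85e-34 and an adjusted p = 0.0228 with an estimated correlation. Among named genes in this list or outside it, Inmt, Cyp2d12, Ugt3a1, Cyp2a4 and Dnase1 were at -6.32 ± 0.23, -5.54 ± 0.26, -4.62 ± 0.32, -4.54 ± 0.29 and -4.71 ± 0.23 (limma adjusted p at most 9.42e-09), where Cyp2 paralogs can share reads. Of the 38 tested fatty acid oxidation genes, 2 rose and 15 fell (3 and 15 adjusted over the list alone, 1 and 26 under median-of-ratios scaling), with a camera adjusted p = 8.33e-14 and an adjusted p = 0.0475 with an estimated correlation. Of the 13 tested genes of the mitochondrial chromosome, 0 rose and 13 fell (0 and 13 adjusted over the list alone, 0 and 13 under median-of-ratios scaling), with a camera adjusted p = 1.98e-20 and an adjusted p = 0.0565 with an estimated correlation. mt-Nd4 was at -1.40 ± 0.13, and under quantile normalization the list did not pass camera (adjusted p = 0.714), with the limit given at day 1. Of the 62 tested nuclear genes of oxidative phosphorylation, 2 rose and 9 fell (0 and 1 adjusted over the list alone, 0 and 42 under median-of-ratios scaling), with a camera adjusted p = 3.83e-10 and an adjusted p = 0.286 with an estimated correlation. On the TPM scale, where every library has the same sum, 11 of these genes were higher and 0 lower, so the direction of their calls depended on the scaling. Relative to all genes their median was lower both as deposited (-0.59) and under median-of-ratios scaling (-0.67). Of the 50 tested ribosomal protein genes, 50 rose and 0 fell (50 and 0 adjusted over the list alone, 35 and 0 under median-of-ratios scaling), with a camera adjusted p = 1.81e-15 and an adjusted p = 0.165 with an estimated correlation. Of the 13 tested principal cell genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone, 4 and 1 under median-of-ratios scaling), with a camera adjusted p = 0.081 and an adjusted p = 0.422 with an estimated correlation. Aqp2, the vasopressin-regulated water channel, was at 1.79 ± 0.26.

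At day 14, 18 of 18 genes of MHC class I and 9 of 10 of MHC class II presentation, 16 of 18 of the interferon gamma response, 36 of 38 of the matrix, 22 of 26 of macrophages and 26 of 30 of injury were higher than in sham. None of these lists passed camera with an estimated correlation (adjusted p from 0.0647 to 0.0836). Kap, the androgen-regulated kidney protein (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), measured 299 ± 88.3 FPKM in transplant against 18432 ± 1663 FPKM in sham (log2 fold change -5.98 ± 0.21, SE, limma adjusted p = 1.52e-12). Havcr1 measured 117 ± 23.2 FPKM in transplant against 0.756 ± 0.154 FPKM in sham. Cd74, the invariant chain of MHC class II, was at 2.65 ± 0.20 on the log2 scale. In total 3413 genes were higher and 782 lower (81.4% of calls higher), against 1952 higher and 1430 lower (57.7%) under median-of-ratios scaling. When only the libraries of day 14 entered the fit, 2255 genes were higher. The median SD of a gene was 0.287 and 0.284 in transplant at day 14 and day 1, against 0.203 to 0.220 in the other groups. The main fit uses 1 spread per gene for all groups, so it may understate the spread at those days. A fit on fewer libraries also has less power, and these causes were not told apart.

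Of the 10 tested MHC class II presentation genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, 9 and 0 under median-of-ratios scaling), with a camera adjusted p = 7.71e-09 and an adjusted p = 0.0648 with an estimated correlation. Of the 18 tested MHC class I presentation genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone, 15 and 0 under median-of-ratios scaling), with a camera adjusted p = 1.48e-08 and an adjusted p = 0.0648 with an estimated correlation. B2m and H2-K1 were at 1.49 ± 0.17 and 1.57 ± 0.19. Of the 18 tested interferon gamma response genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone, 15 and 0 under median-of-ratios scaling), with a camera adjusted p = 3.63e-07 and an adjusted p = 0.0836 with an estimated correlation. Irgm1 and Gbp2 were at 1.20 ± 0.15 and 1.87 ± 0.26. Of the 25 tested type I interferon response genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone, 15 and 0 under median-of-ratios scaling), with a camera adjusted p = 4.76e-06 and an adjusted p = 0.0648 with an estimated correlation. Of the 5 tested T cell genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, 4 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.0432 and an adjusted p = 0.0958 with an estimated correlation. With a pseudocount of 0.1, without sham day 14 replicate 1 or without transplant day 14 replicate 3, the T cell list did not pass camera (adjusted p = 0.104, 0.0748 and 0.0531). Nor did it pass camera with only the groups compared, without genes of the mitochondrial chromosome or on the TPM scale (adjusted p = 0.0538, 0.0570 and 0.0881). Cd3g, Tcf7 and Cd3d were at 1.53 ± 0.31, 1.27 ± 0.27 and 1.03 ± 0.24. Cd3e was below the filter, with 1.0, 0 and 0.147 FPKM in the 3 transplant libraries of day 14 and 0, 0.135 and 0 FPKM in sham. Of the 7 tested dendritic cell genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, 5 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.00303 and an adjusted p = 0.109 with an estimated correlation. Itgax was at 1.90 ± 0.24. Of the 26 tested monocyte and macrophage genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone, 21 and 1 under median-of-ratios scaling), with a camera adjusted p = 2.17e-11 and an adjusted p = 0.0648 with an estimated correlation. Of the 15 tested complement genes, 12 rose and 0 fell (12 and 1 adjusted over the list alone, 12 and 1 under median-of-ratios scaling), with a camera adjusted p = 1.29e-06 and an adjusted p = 0.0579 with an estimated correlation. C3 was at 5.25 ± 0.35. Of the 24 tested cytokine and chemokine genes, 17 rose and 0 fell (20 and 0 adjusted over the list alone, 17 and 0 under median-of-ratios scaling), with a camera adjusted p = 1.06e-08 and an adjusted p = 0.0648 with an estimated correlation. Of the 7 tested neutrophil genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 0 under median-of-ratios scaling), with a camera adjusted p = 0.983 and an adjusted p = 0.988 with an estimated correlation.

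Of the 38 tested extracellular matrix genes, 36 rose and 0 fell (37 and 0 adjusted over the list alone, 35 and 0 under median-of-ratios scaling), with a camera adjusted p = 2.13e-23 and an adjusted p = 0.0648 with an estimated correlation. Mgp and Col3a1 were at 3.40 ± 0.21 and 3.65 ± 0.27. Of the 30 tested tubular injury genes, 26 rose and 0 fell (26 and 0 adjusted over the list alone, 25 and 0 under median-of-ratios scaling), with a camera adjusted p = 5.46e-19 and an adjusted p = 0.0647 with an estimated correlation. Lcn2, Spp1 and Vcam1 were at 5.61 ± 0.31, 4.12 ± 0.16 and 4.45 ± 0.24. Ugt1a2, Ugt1a10 and Aoc1, which degrades diamines, rose to 6.14 ± 0.34, 4.41 ± 0.61 and 5.03 ± 0.42, where Ugt1a genes share exons and single members are uncertain. Of the 40 tested proximal tubule transporter genes, 3 rose and 17 fell (3 and 18 adjusted over the list alone, 2 and 20 under median-of-ratios scaling), with a camera adjusted p = 1.21e-16 and an adjusted p = 0.0648 with an estimated correlation. Slc34a1 was at -0.76 ± 0.18, a call lost under quantile normalization (-0.53, limma adjusted p = 0.0607). Slc22a6, Slc22a7, Slco1a1 and Slc7a13 were at -1.80 ± 0.21, -3.45 ± 0.33, -5.68 ± 0.22 and -5.31 ± 0.16. Of the 35 tested genes of solute and drug metabolism, 0 rose and 23 fell (1 and 23 adjusted over the list alone, 0 and 24 under median-of-ratios scaling), with a camera adjusted p = 3.33e-22 and an adjusted p = 0.0579 with an estimated correlation. Other falls, in this list or outside it, were Acsm3, Akr1c14, Pzp and Nat8f5 at -4.18 ± 0.22, -4.55 ± 0.32, -3.79 ± 0.19 and -3.52 ± 0.33 (limma adjusted p at most 6.48e-07).

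Of the 14 tested heat shock genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone, 0 and 7 under median-of-ratios scaling), with a camera adjusted p = 3.93e-07 and an adjusted p = 0.0579 with an estimated correlation. The median of the list was -0.62, and in sham alone it rose by 0.59 from day 1 and by 0.45 from day 7 to day 14, so much of this difference lay in sham. Hspd1 and Hsp90aa1 were at -0.83 ± 0.10 and -1.05 ± 0.16. Hsph1 was at -1.53 ± 0.17, but its sham mean was higher at day 14 than at day 1 (80.8 against 34.8 FPKM), while transplant held 26.8 and 32.5 FPKM. Of the 26 tested genes of the unfolded protein and integrated stress responses, 1 rose and 8 fell (1 and 8 adjusted over the list alone, 0 and 12 under median-of-ratios scaling), with a camera adjusted p = 6.56e-06 and an adjusted p = 0.0805 with an estimated correlation. The median of this list was -0.15, and in sham alone it rose by 0.25 from day 1 and by 0.23 from day 7 to day 14, so much of this difference also lay in sham. Hspa5, the main chaperone of the endoplasmic reticulum, was at -1.08 ± 0.17. Of the 16 tested thick ascending limb genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, 2 and 2 under median-of-ratios scaling), with a camera adjusted p = 0.869 and an adjusted p = 0.981 with an estimated correlation. Of the 13 tested distal convoluted and connecting tubule genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, 2 and 1 under median-of-ratios scaling), with a camera adjusted p = 0.891 and an adjusted p = 0.981 with an estimated correlation. Among genes of the distal nephron as a whole, Egf and Pvalb were at -1.31 ± 0.20 and -1.84 ± 0.22, and the calcium channel Trpv5 was at 1.88 ± 0.26. Of the 35 tested cell cycle genes, 16 rose and 0 fell (22 and 0 adjusted over the list alone, 12 and 0 under median-of-ratios scaling), with a camera adjusted p = 6.35e-04 and an adjusted p = 0.377 with an estimated correlation. Mki67 was at 1.40 ± 0.30. Of the 50 tested ribosomal protein genes, 45 rose and 0 fell (48 and 0 adjusted over the list alone, 16 and 0 under median-of-ratios scaling), with a camera adjusted p = 3.65e-11 and an adjusted p = 0.22 with an estimated correlation. Umod, Cpt1a and Ppargc1a were at 0.39 ± 0.17, -0.20 ± 0.16 and 0.09 ± 0.17 and did not pass the test.

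**Figure D3:**
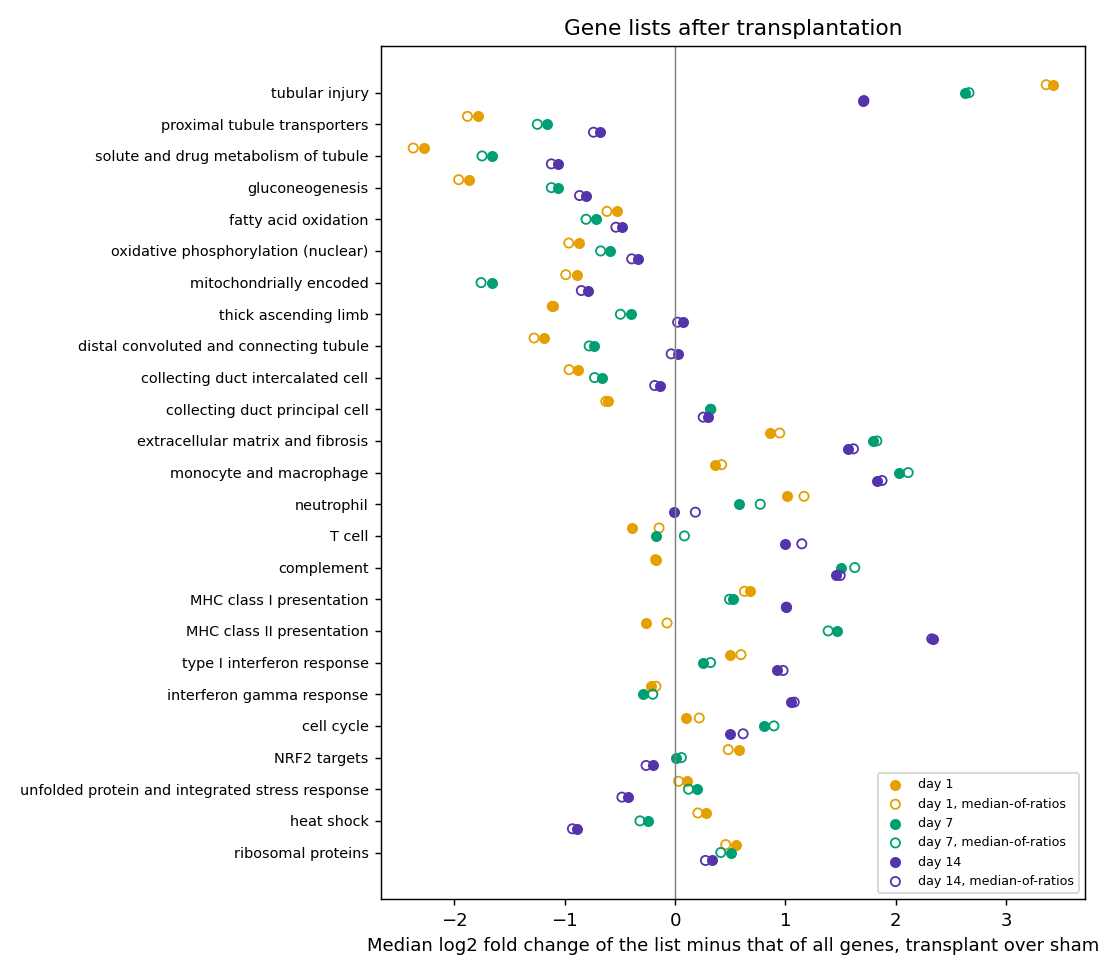
Each row is a gene list fixed beforehand, and the horizontal axis is its median log2 fold change, transplant over sham, minus that of all genes, for day 1, day 7 and day 14 (colours), with FPKM as deposited (filled) and under median-of-ratios scaling (open). Tubular injury lies at 3.43, 2.63 and 1.70, and solute and drug metabolism at -2.28, -1.66 and -1.06.

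Differences of the transplant effect between days are given as signed shifts. A shift up can be a rise that grew or a fall that faded, as for Calb1, which was lower at day 1. A shift down can be a fall that grew or a rise that faded. From day 1 to day 7 the effect was higher for 467 genes and lower for 200 (352 and 257 under median-of-ratios scaling). Slc7a12, an amino acid transporter, Gpc3 and Calb1 shifted up by 4.82 ± 0.71, 3.94 ± 0.36 and 3.73 ± 0.29, as did Ptgds and Serpina1f by 3.60 ± 0.70 and 3.40 ± 0.65. Krt20, Plin2, which coats lipid droplets, and Hmga1 shifted by -4.83 ± 0.51, -3.93 ± 0.34 and -3.74 ± 0.46, and Calcb and Angptl7 by -4.56 ± 0.90 and -4.39 ± 0.69 (limma adjusted p at most 0.00541).

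From day 7 to day 14 the effect was higher for 54 genes and lower for 40, against 71 and 20 under median-of-ratios scaling and 52 and 123 on the TPM scale, so the balance depended on the scaling. Inmt, Ugt1a2, Cyp2d12, Ugt3a1 and Fam151a shifted by 3.48 ± 0.33, 3.17 ± 0.48, 2.72 ± 0.37, 2.71 ± 0.46 and 2.67 ± 0.26. Nat8f5, Fkbp5, a glucocorticoid-induced gene, Alas1, the first enzyme of heme synthesis, and Sdf2l1 shifted by -2.95 ± 0.46, -2.46 ± 0.41, -2.28 ± 0.38 and -2.24 ± 0.45 (limma adjusted p at most 0.0272). Sprr2g was at -3.12 ± 0.69 (limma adjusted p = 0.0457), and its call was lost when any of the 12 libraries but transplant day 14 replicate 1 was left out (0.0755 to 0.116 as limma adjusted p). The call on Sdf2l1 was lost without sham day 7 replicate 1, transplant day 7 replicate 1 or 3, sham day 14 replicate 1 or 2, or transplant day 14 replicate 2 (limma adjusted p from 0.0560 to 0.0918). Transplant day 14 replicate 1 correlated better with the 3 transplant libraries of day 7 (0.977, 0.985 and 0.981) than with the other 2 of its own group (0.976 and 0.9745), and without it 65 genes were higher and 66 lower. Over all libraries left out 1 at a time, 25 to 65 genes were higher and 11 to 66 lower.

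From day 1 to day 14 the effect was higher for 794 genes and lower for 772 (938 and 617 under median-of-ratios scaling). Slc7a12, Ugt1a2, Egf, Calb1 and Hao2, a peroxisomal oxidase, shifted up by 5.72 ± 0.71, 5.14 ± 0.48, 4.20 ± 0.28, 4.12 ± 0.29 and 4.05 ± 0.42. Krt20, Calcb, S100a9, Kap and Plin2 shifted by -6.29 ± 0.51, -4.62 ± 0.90, -4.53 ± 0.61, -4.42 ± 0.30 and -4.23 ± 0.34 (limma adjusted p at most 0.00277). When only the groups compared entered the fit, 509 genes were lower.

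Many genes were called in the same direction at several days. At all 3 days 1755 genes were higher, where independent lists would share 358, and 422 were lower, where independent lists would share 4.49. Under median-of-ratios scaling 710 were higher and 862 lower, against 39.3 and 25.1 for independent lists, so which direction was more common depended on the scaling. Havcr1, Lcn2, Spp1, C3 and Col1a1 were among those higher, and Slc34a1, Slc22a6 and Slc7a13 among those lower. Opposite calls were found for 58 genes between day 1 and day 7, 19 between day 7 and day 14, and 79 between day 1 and day 14. Each day had its own sham libraries, so these lists share no control. They do share 1 estimate of each gene's spread, so genes of small spread can be called at several days. The numbers for independent lists are therefore only a reference.

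Among sham libraries alone, limma called 0 genes between day 1 and day 7 and 0 between day 7 and day 14, with 375 and 570 genes at an unadjusted p under 0.05. Between day 1 and day 14 it called Hsph1, a heat shock protein, which measured 80.8 ± 18.4 FPKM at day 14 and 34.8 ± 7.29 FPKM at day 1 (log2 fold change 1.19 ± 0.17, limma adjusted p = 0.0366), with 746 genes at an unadjusted p under 0.05. The call on Hsph1 was lost without sham day 1 replicate 1 or 2 or sham day 14 replicate 1 or 2 (limma adjusted p from 0.0874 to 0.253).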

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

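The results in this part are those for which the effect of transplantation differed between days by a test of the difference itself. Contrasts between days were fixed before the data were examined, but the list tests fixed then were for transplant against sham only. The counts of splits by whether a transplant library moved, and the sham medians of gene lists, were chosen only after the results were seen. From day 1 to day 7, the log2 effect (± SE) on Havcr1 shifted by -2.18 ± 0.29, while those on Slc34a1, Ppargc1a, C3, Adgre1 and Mki67 shifted by 1.22 ± 0.26, 1.43 ± 0.24, 2.59 ± 0.49, 2.11 ± 0.41 and 1.94 ± 0.43 (limma adjusted p at most 0.0121). Between day 1 and day 14, Havcr1 and Lcn2 shifted by -3.23 ± 0.29 and -2.27 ± 0.43, and Slc34a1, Ppargc1a, C3, Ccl2, Adgre1 and Mki67 by 1.94 ± 0.26, 1.17 ± 0.24, 1.76 ± 0.49, 2.0 ± 0.50, 1.36 ± 0.41 and 1.57 ± 0.43 (limma adjusted p at most 0.043).

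Gene lists differed between days in camera with an estimated correlation, and values are the median log2 shift of the members. From day 1 to day 7, complement shifted by 1.54 (adjusted p = 0.0159) and NRF2 targets by -0.45 (adjusted p = 0.017). From day 7 to day 14, distal convoluted and connecting tubule genes shifted by 0.46 (adjusted p = 0.036), T cell genes by 0.81 (adjusted p = 0.0301), interferon gamma response genes by 1.09 (adjusted p = 0.0301), genes of the unfolded protein and integrated stress responses by -0.62 (adjusted p = 0.0301) and heat shock genes by -0.75 (adjusted p = 0.0301). Between day 1 and day 14, thick ascending limb genes shifted by 1.47 (adjusted p = 0.0258), distal convoluted and connecting tubule genes by 1.22 (adjusted p = 0.0192), intercalated cell genes by 0.71 (adjusted p = 0.028) and T cell genes by 1.11 (adjusted p = 0.028). Over the same days MHC class II genes shifted by 2.16 (adjusted p = 0.0258), complement by 1.22 (adjusted p = 0.0192), heat shock genes by -0.95 (adjusted p = 0.0192) and NRF2 targets by -0.65 (adjusted p = 0.0192). In sham alone the median heat shock gene rose by 0.45 from day 7 to day 14 and by 0.59 from day 1 to day 14, so much of the heat shock shifts lay in the sham libraries. The median gene of the unfolded protein and integrated stress responses also rose in sham, by 0.23 from day 7 to day 14, a part of that list's shift. Only 5 T cell genes were tested. A gene can pass the filter through the transplant libraries of day 14 alone, which favours T cell shifts toward day 14. At day 14 itself, the T cell list lost its call under several settings.

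Other splits of the same libraries were fitted for each comparison, and for differences between days 100 of the 200 splits, with day labels permuted within each surgery, were drawn. With the real split counted, 9 of 100 reached the 667 genes called for day 1 to day 7 (highest other 1041), 1 of 100 the 94 genes for day 7 to day 14 (highest other 85), and 8 of 100 the 1566 genes for day 1 to day 14 (highest other 2082). Each of the other splits as large kept the transplant libraries at their real days and exchanged only sham libraries, which hardly differed between days. Splits that moved a transplant library (91, 92 and 90 of those drawn, in the same order) called at most 1, 1 and 3 genes, so the transplant libraries decide the count and the shares of 100 neither exclude chance nor show it. The transplant libraries alone have 10 splits per pair of days, too few for a share under 0.05. For transplant against sham, 3 libraries against 3 give 10 splits, too few for a share under 0.05: the real split called 5977, 6336 and 4195 genes at day 1, day 7 and day 14 (1 split each) and the highest other called 1, 0 and 1. For sham between days the 10 splits are also too few: the real split called 0, 0 and 1 genes, reached by 10, 10 and 3 splits, and the highest other called 3, 1 and 2.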

How the results depend on the processing

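Of the counts of genes called higher or lower in the 9 comparisons, those that moved by more than 1.5 times are given here, and the cause was not tested unless a smaller number of genes or libraries gives it. Under median-of-ratios scaling, transplant against sham gave 2365 higher and 2285 lower at day 1, 1985 and 1790 at day 7, and 1952 and 1430 at day 14, and 20 lower from day 7 to day 14. Quantile normalization gave 2282 and 2224, 1887 and 1730, and 1561 and 1337 for the same 3 days. With a log2 fold change of at least 1, they were 1895 and 774, 1934 and 458, and 1439 and 302, with 512 lower from day 1 to day 14, 509 higher at all 3 days and 155 lower at all 3 days. With a mean FPKM of at least 5, fewer genes were tested, and 3589 were higher at day 7, 2049 higher at day 14, and 74 lower from day 7 to day 14. With no filter, differences of the effect had 300 higher from day 1 to day 7 and 19 higher and 8 lower from day 7 to day 14, and sham from day 1 to day 14 had 0 higher.

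With only the groups compared, 2255 genes were higher at day 14, the effect was lower for 509 from day 1 to day 14, and sham had 1 higher from day 1 to day 7 and 0 from day 1 to day 14. Array weights gave 86 lower from day 7 to day 14 and, in sham, 6 higher from day 7 to day 14 and 4 from day 1 to day 14. The settings chosen after seeing the data gave the following. Without genes of the mitochondrial chromosome, sham from day 1 to day 14 had 3 higher. Without the 100 genes most abundant in sham, 2505 were higher at day 1, 2426 higher and 1426 lower at day 7, 2251 higher at day 14, 19 lower from day 7 to day 14, and 2 higher in sham from day 1 to day 14. On the TPM scale 8512 were higher at day 7, 830 higher from day 1 to day 7, 123 lower from day 7 to day 14, and 2 higher in sham from day 1 to day 14.

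Leaving out each library in turn gave 25 to 65 genes higher and 11 to 66 lower for day 7 to day 14, and in sham 0 to 3 higher and 0 to 1 lower from day 1 to day 14, 0 to 1 lower from day 1 to day 7, and 0 to 1 lower from day 7 to day 14. For day 7 to day 14, the 65 and 66 came without transplant day 14 replicate 1, the 25 without transplant day 14 replicate 2 and the 11 without sham day 7 replicate 1. In sham from day 1 to day 14, the 3 came without sham day 14 replicate 3. With fewer libraries a group of 2 remained. Each other count stayed within 1.5 times. Atp5b at day 7 and mt-Cytb at day 14 changed sign under quantile normalization, to 0.23 and 0.10 on the log2 scale, without passing the test (limma adjusted p = 0.0828 and 0.473). With an estimated correlation in camera, 58 of 117 list results lost their call and 59 kept their side of the threshold. Under other settings, list calls were gained and lost as follows: 16 and 2 with no filter, 1 and 11 with a mean FPKM of at least 5, 8 and 1 under median-of-ratios scaling, 9 and 6 under quantile normalization, 8 and 2 without the 100 most abundant genes, 2 and 3 on the TPM scale, and at most 2 either way under each other setting but leaving out 1 library (7 and 11 in all).

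The replicate numbers were not taken as pairs: of the 9 pairs of same-numbered libraries within a day, 1 had a correlation of deviations above 0.1 (range -0.04 to 0.10), and 4 of 9 transplant libraries correlated best with the sham library of their own number. With the number as a replicate block, sham from day 1 to day 14 had 0 higher, and each other count stayed within 1.5 times. Depth is unknown, so what it limits could not be given.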

Other observations

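Other lists fixed beforehand describe further parts of the tissue, with counts under median-of-ratios scaling in parentheses after each. Among called genes at day 1, endothelial genes had 11 higher and 0 lower of 21 tested (3 higher and 2 lower), with Egfl7 at 0.87 ± 0.16 and Pecam1 at 0.79 ± 0.17 on the log2 scale, and at day 7 they had 6 higher and 0 lower (0 higher and 1 lower). Podocyte genes had 6 higher and 1 lower of 14 at day 1 (2 higher and 2 lower), with Nes at 1.07 ± 0.18. Glycolysis genes had 8 higher and 1 lower of 17 at day 1 (6 higher and 1 lower) and 10 higher and 0 lower at day 7 (6 higher and 0 lower), with Pfkp at 1.68 ± 0.16 and Hk1 at 1.07 ± 0.15 at day 7. None of these lists passed camera with an estimated correlation (adjusted p from 0.423 to 0.902).

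Called cholesterol synthesis genes were mostly lower at day 1 and mostly higher at day 7, though the list did not pass camera with an estimated correlation (adjusted p = 0.365 and 0.688). At day 1, 2 were higher and 6 lower of 22 (1 higher and 9 lower), with Cyp51 at -2.45 ± 0.17, Idi1 at -2.70 ± 0.22 and Hmgcs1 at -1.57 ± 0.16. At day 7, 11 were higher and 1 lower (7 higher and 3 lower), with Sqle at 1.34 ± 0.18. Ferroptosis and iron genes had 10 higher and 0 lower of 14 at day 1 (7 higher and 1 lower), with Hmox1 at 2.70 ± 0.24 and Acsl4 at 1.64 ± 0.16. Autophagy genes had 6 higher and 5 lower of 29 at day 1 (2 higher and 8 lower), with Sqstm1 at 1.44 ± 0.12 and Gabarapl1 at -1.43 ± 0.13. The ferroptosis and autophagy lists did not pass camera with an estimated correlation at day 1 (adjusted p = 0.175 and 0.394). Of 9 erythrocyte and platelet genes, 5 were higher and 0 lower at day 7 (4 higher and 0 lower), and the list did not pass camera (adjusted p = 0.295, and 0.54 with an estimated correlation). Among them were Hbb-bs at 1.48 ± 0.27 and Hba-a1 at 1.11 ± 0.22, whose paralogs can share reads.

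The tests on the median of all genes, the scaling of ribosomal protein genes and the Y-linked genes were chosen only after the results they bear on were seen. More genes were called higher than lower after transplantation at each of the 3 days. With genes of the mitochondrial chromosome left out and libraries rescaled to the same sum, the lowest of the 3 medians of all genes was 0.297. A shift thus remained that their smaller share cannot give. The rescaling also evened out sums that were lower in transplant as deposited (at day 7, a mean of 397875 against 491941 in sham). How much of the deposited shift their share made up was therefore not measured. With the 100 genes most abundant in sham left out, the medians were 0.08, 0.15 and 0.13. Abundant genes could therefore account for much of the shift, and the part left at day 7 and day 14 stays open (lowest 0.0817). Genes of the mitochondrial chromosome could be among these 100, so this test and the one before it are not separate. The 100 were ranked on sham alone, which can favour genes that fell after transplantation. A real rise of most transcripts cannot be told apart from a change of composition, since FPKM holds no absolute amounts.

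Of 50 ribosomal protein genes, 49, 50 and 45 were higher at day 1, day 7 and day 14, though the list did not pass camera with an estimated correlation (adjusted p = 0.205, 0.165 and 0.22). Against 10000 lists matched on length, GC content and expression, their median lay at the 100th percentile at each day. At day 1 it was 0.86 where matched lists had a median of -0.27 (central 95% from -0.55 to 0.02), which argues against length or GC content alone. The match was incomplete: matched genes were 1.188 times as long, with a median of 150.8 against 173.5 FPKM. Matched lists also lay below all genes at day 1 (median 0.31), so the gap was not due to the ribosomal rise alone. Matched genes were drawn singly, so the percentile does not allow for ribosomal protein genes moving together. Under median-of-ratios scaling 39, 35 and 16 of 50 were higher at day 1, day 7 and day 14, so for day 14 the scaling stays open as part of the cause of the calls (fewest 16). Relative to all genes, the day 14 median was 0.34 as deposited and 0.28 under that scaling, so the place of the list among all genes changed little. Reads shared with ribosomal protein pseudogenes were not tested.

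Kap, Slco1a1, Slc7a13, Cyp7b1 and Acsm3, known to be higher in male than in female mouse kidney, were among the genes that fell. Slc7a12, known to be higher in female kidney, shifted up between day 1 and day 14. Slc7a13, Cyp7b1 and Acsm3 had already fallen at day 1, and most of the Slc7a12 shift came by day 7. A shift does not tell whether Slc7a12 rose above sham or a fall faded. The hypothesis that sex hormone drive on the tubule was weaker by day 14 was tested on 8 other genes known as higher in male kidney, named before their values were looked at here: their median was -1.28, -1.39 and -2.22 at day 1, day 7 and day 14, and minus that of 75 proximal tubule genes it was 0.46, -0.37 and -1.68, a move that came more from the rise of the tubule median (-1.74 to -0.53) than from the male list. At day 14, 6 of the 8 were lower, for example Cyp2j13 at -3.23 ± 0.25, but 5 were already lower and Gusb higher at day 1 and at day 7, and Slc22a30 and Slc22a28 fell less at day 14 (-2.45 ± 0.27 and -2.23 ± 0.31) than at day 1 (-3.53 ± 0.27 and -3.56 ± 0.31). Prlr and Abcc3, known as higher in female kidney, had a mean of -0.17, 1.05 and 2.22 relative to all genes at day 1, day 7 and day 14, with Abcc3 no higher at day 14 (1.99 ± 0.31) than at day 7 (2.04 ± 0.31). In sham at day 14, Abcc3 measured 0.029 ± 0.051 FPKM, so it could not show a loss, and Prlr measured 2.77 ± 2.23 FPKM. A loss of proximal tubule transcripts alone would lower the mean, and the day 14 mean rose. Since only Prlr could have shown a loss, this argues only weakly against a loss alone. Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty had a mean of 0.0124 relative to all genes at day 14, and mean Xist was 0.033 FPKM in transplant and 0 in sham. This argues against kidney tissue of another sex in the transplant libraries. The sex of the recipient is not stated, and these genes do not tell it. Weaker androgen action is left as a candidate, with hormone levels not measured here and injury acting on the male-biased genes by another route left open.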
